A study of Homo sapiens with 16 samples.

How the data were processed

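Polyadenylated RNA of SH-SY5Y cells was made into libraries with a directional kit, per the labels' protocols, and the deposited table holds 1 column per library. Its values are counts of reads per gene in HTSeq's layout, per the file headers and the submitters' processing notes, which name STAR and HTSeq with no versions and the builds GRCh38.p13 and hg38. The strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes may be mixed. The table has 69222 gene rows, of which 32387 hold no count in any library, and 5 summary rows for reads without a gene. Reads placed at more than 1 position were counted in a summary row, so genes with near-identical copies, such as ribosomal protein genes, metallothioneins and HSPA6, are uncertain. Gene symbols came from a table of gene names that matched 62639 IDs.

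Everything else was computed from those counts in R 4.3.3. Genes were kept by edgeR's default expression filter over the 8 groups, which left 18081, and libraries were scaled by the trimmed mean of M values. A quasi-likelihood model with 1 mean per group and robust spread was fitted over all 16 libraries with edgeR 4.0.16, which leaves 8 residual degrees of freedom, so that groups of 2 share 1 estimate of the spread. Contrasts compared differentiated with untreated plates, each film with plates, films with each other, stimulated with unstimulated films, and stimulated films with plates. The mean effect of stimulation and its difference between films were tested in the same model. A gene was called at a Benjamini-Hochberg adjusted p of at most 0.05, and standard errors are the log2 fold change divided by the root of F. Levels are given as CPM from edgeR, which use the scaled library sizes.

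Gene lists, 35 with 833 matched genes, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, again with the correlation estimated, and with fry. The lists, the tests, the rule for named genes and all but the last 2 kinds of alternative below were fixed before the data were examined. The rule took, per main comparison, the 5 largest rises and 5 largest falls among called genes with at least 5 CPM in 1 group, a symbol that is not a clone, non-coding or antisense name and groups that do not overlap, and the 2 smallest p-values from each of the 10 lists with most calls, and 3 of each direction in other comparisons. Further members of the fixed lists are named where a list is described. For the mean effect of stimulation and its difference between films it took up to 5 called genes, and none were called. The labels give replicate numbers 1 and 2 in every group, with the prefix NB33 for every replicate 1 and NB34 for every replicate 2. The meaning of the prefixes is not given in the sources used here, and the main model does not use them.

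Floors of 3 counts over a group and counting intervals cover counting error only. Precision is limited by 2 libraries per group more than by depth: the median standard error of a log2 fold change was 0.25 to 0.26 for comparisons of 2 groups and 0.15 for the mean effect of stimulation. The models were tested on simulated data, with 200 genes changed, 50 at each fold size. Counts were drawn from fitted means, equal in the groups compared apart from the changed genes, with 1 spread per gene for all libraries. The coefficient of variation between real replicates ran from 6.9% to 36.2% over the groups, so recovery and false calls in the data may differ. The changed genes were picked above a minimum mean level, so recovery of weakly expressed genes was not measured. For the P(rGO) film against plates 42.0% of genes changed 2-fold and 84.0% of those changed 4-fold were recovered, and for the mean effect of stimulation 86.0% and 100%. False calls were 2 of 106 for the film and 12 of 179 for the mean effect.

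Alternatives were relative log expression scaling, no low-count filter, a replicate block, DESeq2 1.42.0, a fit of only the groups compared, and leaving out each replicate in turn. Fits without the untreated libraries and with the 12 film libraries alone were added after seeing the data. No library was left out of the main results.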

Results

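SH-SY5Y is a human neuroblastoma cell line that stops dividing and extends neurites when it is grown with retinoic acid and the neurotrophin BDNF. Polyadenylated RNA was sequenced from these cells in 8 groups of 2 libraries each, 16 libraries in all. An untreated group and a differentiated group were grown on culture plates. The other 6 groups were differentiated on 1 of 3 electrically conductive films, each without and with electrical stimulation (ES). The films were P(rGO), a composite of a polymer and reduced graphene oxide, PEDOT:PSS, a conducting polymer blend, and ITO, indium tin oxide. Serum was lowered in 3 steps to 5%, 2.5% and 1% on days 2, 3 and 5. Retinoic acid was given at 10 µM from day 3 to day 6, and BDNF was then given at 50 ng/mL for 4 days. Stimulation was a 1 Hz square wave of 0.1 V peak to peak, applied for 8 h per day over the last 4 days. The labels name a coat of poly-L-lysine and laminin for the films and give none for the plates.

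Between 15600410 and 20851000 reads per library were assigned to genes. Of the genes, 18081 had enough counts to be tested. The biological coefficient of variation between the replicates of a group was 36.2% in untreated cells, 18.1% in differentiated cells on plates, and 6.9% to 18.2% in the 6 film groups. In GRCh38 coordinates CYP26B1 lies on chromosome 2 from 72129238 to 72148038, EGR3 on chromosome 8 from 22687659 to 22693302. HMGCS1 lies on chromosome 5 from 43289395 to 43313512, and SLIT1 on chromosome 10 from 96998038 to 97185920, and each count is of reads per gene. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. On the first principal component, which held 45.8% of the variance, differentiated plate replicate 1 lay at -21.0 and replicate 2 at 14.3, and the 12 film libraries lay between 9.4 and 27.5. On the second, which held 12.5%, these plate replicates lay at 53.5 and 34.2, and the 12 film libraries between -27.1 and 4.7.

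**Figure D1:**
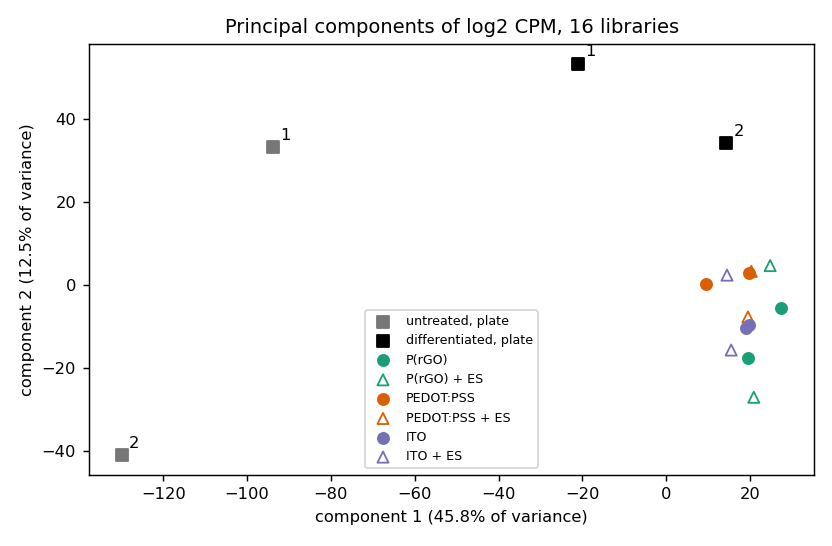
Scores of the 16 libraries on the first 2 principal components of log2 CPM. Each point is 1 library, colours give the surface, squares are plates, circles are films without and triangles films with stimulation, and the numbers beside the plate libraries are replicate numbers. The untreated libraries lie at -93.9 and -129.9 on component 1 and the film libraries between 9.4 and 27.5.

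The first comparison asked what differentiation changed on plates. CYP26B1, which degrades retinoic acid, went from 1.81 ± 2.1 to 814 ± 850 CPM (SD, n = 2; log2 fold change 8.82, SE 1.09, adjusted p = 0.00015). NTRK2, the BDNF receptor and a member of the retinoic acid list, went from 11.8 ± 7.9 to 481 ± 130 CPM (log2 fold change 5.35, SE 0.44, adjusted p = 1.4e-05). The list of BDNF and Trk signalling was not called, with 4 of 13 genes higher, also 4 adjusted over the list alone (list adjusted p = 0.061, 0.17 with an estimated correlation). DPYSL3 (log2 fold change 3.47, SE 0.27) and DCX (1.59, SE 0.23) rose as well, both of which bind the cytoskeleton in growing neurites. CDC20, an activator of the anaphase promoting complex (log2 fold change -2.94, SE 0.42, adjusted p = 0.00042), and AURKA, a mitotic kinase (-2.02, SE 0.29), fell. FN1, the matrix protein fibronectin, fell from 113 ± 2.6 to 11.7 ± 4.6 CPM (log2 fold change -3.27, SE 0.32, adjusted p = 3e-05).

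Of the 12 measured genes of the retinoic acid list, 8 rose, 1 fell and 3 did not pass (adjusted p = 5.8e-09 for the list, 0.14 with an estimated correlation between genes). Adjusted over the list alone 8 rose and 1 fell. CRABP2, a carrier of retinoic acid, and RARB, a retinoic acid receptor, were among those that rose, by 2.79 and 1.99 on the log2 scale. In the neurite list 10 of 24 genes rose and none fell (15 rose adjusted over the list alone; list adjusted p = 7e-07, 0.15 with an estimated correlation). Of 22 voltage-gated channel genes, 12 rose and 1 fell, both over all genes and adjusted over the list alone (list adjusted p = 7e-07, 0.063 with an estimated correlation). SCN9A, a sodium channel, rose, at a log2 fold change of 1.82 (SE 0.25). Synapse and vesicle genes showed 13 rises and 1 fall among 27 (14 and 1 adjusted over the list alone; list adjusted p = 3.1e-05, 0.16 with an estimated correlation). CHGB and SCG2, which are secretory granule proteins, rose by 1.58 (SE 0.22) and 1.92 (SE 0.26). In the cholesterol biosynthesis list 7 of 24 genes rose (9 adjusted over the list alone; list adjusted p = 0.011, 0.50 with an estimated correlation). Its call was lost without untreated replicate 1 (adjusted p = 0.18) and without differentiated plate replicate 2 (0.10).

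Of the 34 cytosolic ribosomal protein genes all 34 fell, over all genes and adjusted over the list alone, by a median of 0.79 on the log2 scale (list adjusted p = 5.3e-13, 0.27 with an estimated correlation). The cell cycle list had 19 falls among 31 genes, also 19 adjusted over the list alone (list adjusted p = 2.9e-11, 0.19 with an estimated correlation). The list of genes typical of mesenchymal neuroblastoma cells had 16 falls among 21, also 16 adjusted over the list alone, and its list test held with an estimated correlation (adjusted p = 0.0084). The extracellular matrix list, where 21 fell and 3 rose of 29 (22 and 4 adjusted over the list alone), held as well (adjusted p = 0.036 with an estimated correlation). So did the nuclear oxidative phosphorylation list, where 22 of 30 fell (24 adjusted over the list alone; adjusted p = 0.039 with an estimated correlation). These 3 were the only ones of the 18 lists called for differentiation that did. Glycolysis genes fell in 13 of 17 cases, GAPDH by 0.92 on the log2 scale (14 adjusted over the list alone; list adjusted p = 9.9e-07, 0.14 with an estimated correlation). Fibroblast markers, which were read as a check on other cell types, fell in 10 of 13 cases (11 adjusted over the list alone; list adjusted p = 1.9e-06, 0.063 with an estimated correlation), COL1A1 from 31.2 ± 0.67 to 2.00 ± 0.21 CPM.

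The largest falls by the rule for named genes included KIRREL1 and CCL2, which had no count in either differentiated plate library. Set against a floor of 3 counts over the group, KIRREL1 was at least 78.2-fold lower and CCL2, a chemokine, at least 69.8-fold lower. COLCA1 had 2 counts in untreated cells and 2235 in differentiated cells, a ratio of 972 with a counting interval (95%) from 269 to 8027. The differentiated replicates differed widely, at 56.6 ± 51 CPM (SD, n = 2). In all, edgeR's quasi-likelihood test called 5353 of 18081 genes at an adjusted p of at most 0.05, 2495 higher and 2858 lower. The count rested on the replicates: it was 1767 without differentiated plate replicate 2 and 8050 without untreated replicate 1, and 320 when only these 4 libraries were fitted. CYP26A1 lost its call without differentiated plate replicate 2 or without either untreated replicate.

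**Figure D2:**
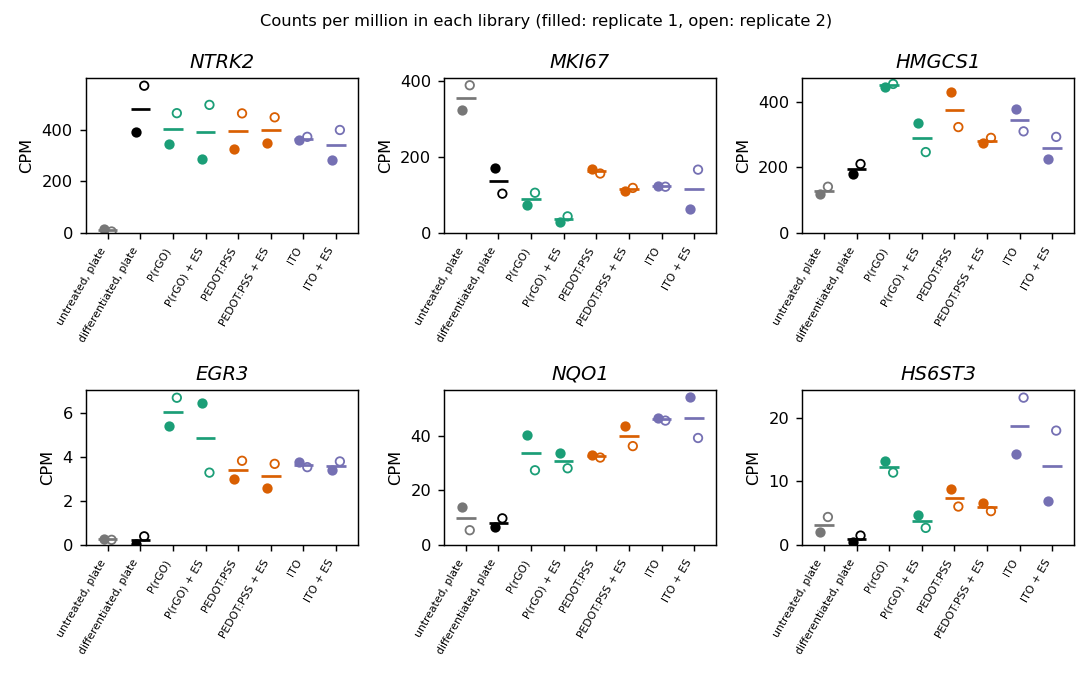
CPM of 6 genes in each of the 16 libraries. Filled points are replicate 1, open points replicate 2, and the bar is the mean of the 2. NTRK2 is higher in all differentiated groups than in untreated cells, and HMGCS1, EGR3, NQO1 and HS6ST3 are higher in the unstimulated film libraries than in the differentiated plate libraries.

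The next comparisons asked what each film changed in differentiated cells without stimulation, against differentiated cells on plates. EGR3, an immediate early transcription factor, rose on all 3 films, from 0.227 ± 0.24 CPM on plates to 6.08 ± 0.90 on P(rGO) (log2 fold change 4.67, SE 0.53, adjusted p = 0.00045). It was at 3.42 ± 0.59 on PEDOT:PSS (3.84, SE 0.54, adjusted p = 0.0041) and 3.67 ± 0.17 on ITO (3.94, SE 0.54, adjusted p = 0.0013). HMGCS1, an early enzyme of cholesterol synthesis, rose from 195 ± 22 CPM to 451 ± 5.6 on P(rGO), 377 ± 76 on PEDOT:PSS and 344 ± 48 on ITO. SLIT1, an axon guidance ligand, fell from 251 ± 16 CPM to 39.1 ± 1.3, 68.1 ± 1.1 and 36.5 ± 5.9 on the same films. EPAS1, a hypoxia-inducible transcription factor, fell on all 3 films, with log2 fold changes of -4.30 on P(rGO), -3.62 on PEDOT:PSS and -3.9 on ITO. These differences were measured against plate libraries that differ from each other: replicate 1 had 8.58% mitochondrially encoded and 5.62% ribosomal protein counts, and replicate 2 had 5.42% and 4.17%.

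On P(rGO), 838 genes were called, 541 higher and 297 lower. The cholesterol biosynthesis list had 13 rises among 24 genes and no fall (18 adjusted over the list alone; list adjusted p = 5e-18, 0.20 with an estimated correlation). SC5D rose, at a log2 fold change of 0.84 (SE 0.13) and HMGCS1 at 1.21 (SE 0.19). Immediate early genes rose in 9 of 26 cases (12 adjusted over the list alone; list adjusted p = 3.4e-12, 0.23 with an estimated correlation). DUSP5, a phosphatase induced by growth signals, was among them (2.92, SE 0.34). The oxidative stress list had 8 rises among 24 (12 adjusted over the list alone; list adjusted p = 3.2e-09, 0.23 with an estimated correlation). NQO1, a quinone reductase, went from 8.18 ± 2.3 to 33.9 ± 9.2 CPM. Ribosomal protein genes fell in 12 of 34 cases (34 adjusted over the list alone; list adjusted p = 7.7e-22, 0.24 with an estimated correlation), RPLP0 by 0.98 on the log2 scale. The 31 cell cycle genes had 3 falls, also 3 adjusted over the list alone (list adjusted p = 1.1e-06, 0.47 with an estimated correlation). CDH11, a cadherin, rose by 1.96 (SE 0.20), and LUM, a matrix proteoglycan, rose by 3.47 (SE 0.37). Of 13 fibroblast markers 2 rose and 1 fell (3 and 1 adjusted over the list alone; list adjusted p = 0.0031, 0.23 with an estimated correlation). Of 21 genes typical of mesenchymal neuroblastoma cells 4 rose and 1 fell (6 and 1 adjusted over the list alone; list adjusted p = 0.0063, 0.23 with an estimated correlation), and the call was lost without plate replicate 2 (0.067).

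On PEDOT:PSS, 267 genes were called, 185 higher and 82 lower. SGK1, a kinase induced by serum and glucocorticoids, had the largest rise among genes with at least 5 CPM, from 11.1 ± 6.7 to 102 ± 20 CPM (log2 fold change 3.19, SE 0.35, adjusted p = 0.0011), and INHBA, a subunit of activin, rose by 2.89 (SE 0.41). VGF, a neurotrophin-induced secretory protein, rose from 1340 ± 520 to 4920 ± 340 CPM (1.88, SE 0.43, adjusted p = 0.045). KIT, a receptor tyrosine kinase, fell by 4.16 on the log2 scale and RTN4RL1, a receptor related to that of an axon growth inhibitor, by 4.11. In the cholesterol list 3 of 24 genes rose (16 adjusted over the list alone; list adjusted p = 3.4e-16, 0.15 with an estimated correlation). In the immediate early list it was 5 of 26 (9 adjusted over the list alone; list adjusted p = 7.6e-11, 0.25 with an estimated correlation). Fibroblast markers had 1 rise and 1 fall among 13 (3 and 1 adjusted over the list alone; list adjusted p = 0.0054, 0.29 with an estimated correlation). The mesenchymal neuroblastoma list had 3 rises among 21 (4 rises and 1 fall adjusted over the list alone; list adjusted p = 7e-04, 0.15 with an estimated correlation). None of the 34 ribosomal protein genes passed over all genes, and 18 fell adjusted over the list alone (list adjusted p = 3.1e-15, 0.32 with an estimated correlation).

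On ITO, 764 genes were called, 452 higher and 312 lower. ID1, a target of BMP signals, rose by 3.73 (SE 0.78, adjusted p = 0.016). NEUROG2, a proneural transcription factor, fell by 4.71 on the log2 scale and SPOCK1, a matrix proteoglycan, by 5.01. Immediate early genes rose in 10 of 26 cases (11 adjusted over the list alone; list adjusted p = 1.2e-12, 0.20 with an estimated correlation). Oxidative stress genes rose in 7 of 24 (10 adjusted over the list alone; list adjusted p = 6.8e-10, 0.20 with an estimated correlation). Cholesterol genes rose in 6 of 24 (17 adjusted over the list alone; list adjusted p = 7.3e-12, 0.17 with an estimated correlation). Ribosomal protein genes fell in 12 of 34 cases (32 adjusted over the list alone; list adjusted p = 2.1e-22, 0.23 with an estimated correlation). Of 21 genes typical of mesenchymal neuroblastoma cells 6 rose and 1 fell (10 and 1 adjusted over the list alone; list adjusted p = 2.2e-06, 0.13 with an estimated correlation). Of 13 fibroblast markers 4 rose and 1, PDGFRA, fell (8 and 1 adjusted over the list alone; list adjusted p = 7.9e-05, 0.17 with an estimated correlation).

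The counts against plates fell furthest without plate replicate 1. Without it, 100 genes were called for P(rGO), 19 for PEDOT:PSS and 132 for ITO, and without plate replicate 2 the counts were 1023, 312 and 817. Of the genes named by the rule, 14 of 28 for P(rGO), 22 of 27 for PEDOT:PSS and 10 of 26 for ITO lost their call without plate replicate 1, among them HMGCS1 on each film. The cell cycle list then lost its call on P(rGO) (adjusted p = 0.20) and changed direction on ITO, from a median of -0.36 and 1 fall among 31 genes (3 adjusted over the list alone; list adjusted p = 0.0041, 0.58 with an estimated correlation) to adjusted p = 0.40. EGR3 and EPAS1 kept their calls on P(rGO) and lost them on PEDOT:PSS, and SLIT1 and CDH11 kept theirs on both. A left-out film library ended calls too: 171 and 190 genes were called without P(rGO) replicate 1 or 2, 51 and 28 without PEDOT:PSS replicate 1 or 2, and 313 and 188 without ITO replicate 1 or 2. VGF and EPAS1 on PEDOT:PSS lost their calls without either film library, VGF also without either plate library, and ID1 on ITO without ITO replicate 2 or either plate library.

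Of the genes called, 184 were higher and 80 lower on both P(rGO) and PEDOT:PSS, 345 and 210 on both P(rGO) and ITO, and 178 and 77 on both PEDOT:PSS and ITO, with no gene called in opposite directions. Independent lists of these sizes would share 5.5 and 1.3, 13.5 and 5.1, and 4.6 and 1.4 genes. In 20 simulations of unchanged films, with plate and film libraries redrawn from fitted means, the mean overlaps were 0. Unchanged films leave hardly any gene to call, so that 0 was close to fixed in advance and decides nothing. The fold changes of film pairs correlated across genes at 0.83, 0.82 and 0.81 (covariances 0.35, 0.39 and 0.34), against 0.48 (covariance 0.09) in the simulations. Genes are not independent replicates. The simulations gave plates and films the same spread per gene. The coefficient of variation was 18.1% on differentiated plates and 9.1%, 7.5% and 11.8% on unstimulated P(rGO), PEDOT:PSS and ITO. Noisier shared plates raise such a correlation, so 0.48 is too low a mark for sharing. The plate libraries are too few to split with 2 in each part, so part of the likeness may come from sharing them. Called on all 3 films were 253 genes, 177 higher and 76 lower. Among them were KIT, RTN4RL1, SGK1, INHBA, VGF, NEUROG2 and SPOCK1, each described above for a single film.

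**Figure D3:**
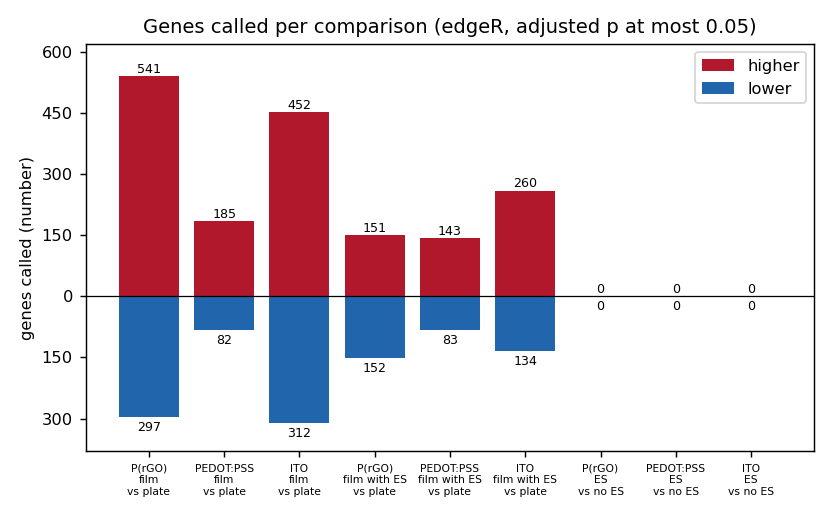
Numbers of genes called for each film against differentiated plates, without and with stimulation, and for stimulation on each film. Bars above 0 count genes that were higher and bars below 0 genes that were lower. Stimulation has 0 calls on each film, and P(rGO) without stimulation has 541 higher and 297 lower.

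The films were also compared with each other without stimulation. EdgeR called 0 genes between PEDOT:PSS and P(rGO) (243 at an unadjusted p under 0.05), 0 between ITO and P(rGO) (299) and 0 between PEDOT:PSS and ITO (283), where DESeq2 called 0, 0 and 2. The cell cycle list lay higher on PEDOT:PSS than on P(rGO) in 31 of 31 genes, by a median of 0.69 (list adjusted p = 2.5e-34, 0.34 with an estimated correlation). It lay higher than on ITO in 31 of 31, by 0.42 (2.9e-11, 0.78 with an estimated correlation). No gene of it passed over all genes or adjusted over the list alone. Without ITO replicate 1, 9 genes were called between ITO and P(rGO) and 10 between PEDOT:PSS and ITO.

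The main question of the series was what stimulation changed on each film. The genes of the cell cycle list lay lower with stimulation on P(rGO), 29 of 31 of them, with a median log2 fold change of -0.69 (list adjusted p = 3.1e-15, 0.34 with an estimated correlation). MKI67, a proliferation marker, stood at 37.1 ± 9.8 CPM with stimulation and 89.7 ± 23 without. On the same film fibroblast markers had a median of -0.16, with 0 of 13 past the test over all genes and 2 lower adjusted over the list alone (list adjusted p = 0.014, 0.34 with an estimated correlation). That call was lost without unstimulated P(rGO) replicate 1 (0.10) or stimulated replicate 2 (0.40). The share of uniquely placed reads assigned to no gene was 9.48% ± 0.75 with stimulation and 7.54% ± 0.37 without (SD, n = 2). Such reads may still lie within genes, in introns or on the other strand, since the counting settings are not given. On PEDOT:PSS the median of the cell cycle list was -0.49 (list adjusted p = 1e-13, 0.76 with an estimated correlation) and on ITO 0.06, where the difference in effect from P(rGO) had an adjusted p of 3.3e-17 for that list (0.52 with an estimated correlation). Cholesterol biosynthesis genes lay lower on all 3 films, with medians of -0.32 on P(rGO) (list adjusted p = 5.2e-08, 0.34 with an estimated correlation), -0.19 on PEDOT:PSS (3e-05, 0.82 with an estimated correlation) and -0.34 on ITO. There all 24 were lower (3e-15, 0.28 with an estimated correlation). HMGCS1 stood at 291 ± 62 CPM with stimulation and 451 ± 5.6 without on P(rGO), 282 ± 12 and 377 ± 76 on PEDOT:PSS, and 259 ± 48 and 344 ± 48 on ITO. No single gene of the cell cycle and cholesterol lists passed on a film, over all genes or adjusted over the list alone. For the mean effect over the 3 films 8 cholesterol genes fell adjusted over the list alone and 0 over all genes (list adjusted p = 8.8e-17, 0.22 with an estimated correlation).

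The metal response list, which holds the metallothioneins, lay higher on each film, with medians of 0.29, 0.25 and 0.47 on P(rGO), PEDOT:PSS and ITO (list adjusted p = 0.039, 0.030 and 0.00043; 0.34, 0.76 and 0.28 with an estimated correlation). No gene of it passed over all genes; adjusted over the list alone 2 rose on P(rGO) and 0 on PEDOT:PSS and ITO. MT2A, a metallothionein with close paralogs, was at 20.4 ± 19 CPM with stimulation and 3.99 ± 2.6 without on P(rGO), and at 18.7 ± 22 and 3.71 ± 1.4 on ITO. The list's call was lost on P(rGO) without stimulated replicate 1 (adjusted p = 0.53) or unstimulated replicate 2 (0.13), on PEDOT:PSS without stimulated replicate 1 (0.12) or unstimulated replicate 2 (0.10), and on ITO without stimulated replicate 1 (0.57). The heat shock list was called higher on ITO (median 0.20, adjusted p = 0.0018, 0.91 with an estimated correlation) and changed direction, with adjusted p = 0.79, without stimulated ITO replicate 1, and lost its call without unstimulated ITO replicate 2 (0.26). Without stimulated P(rGO) replicate 2, 6 of the 9 lists called on P(rGO) were lost, the cholesterol list among them (adjusted p = 0.099), and on PEDOT:PSS that list was lost without unstimulated replicate 1 (0.50). Ribosomal protein genes lay higher on P(rGO) (median 0.24, adjusted p = 6.6e-08, 0.62 with an estimated correlation) and on ITO (0.18, adjusted p = 9.1e-08, 0.91 with an estimated correlation).

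With all 16 libraries and no replicate block, edgeR called 0 genes on P(rGO) (986 at an unadjusted p under 0.05), 0 on PEDOT:PSS (126) and 0 on ITO (293). For the mean effect over the 3 films it called 0 (1021), and DESeq2 called 14, 0, 0 and 7 in the same order. Evenly spread p-values would give 904 genes under 0.05. Other splits of the libraries within films gave a median of 245 for the mean effect. Such splits can put stimulated and unstimulated libraries in 1 group, where a real effect would enter the spread. Neither 904 nor 245 is therefore known to be the level without change in this model. ENC1, an actin-binding protein of neurons, had the smallest p on P(rGO), at 34.6 ± 4.8 CPM with stimulation and 168 ± 39 without (log2 fold change -2.28, adjusted p = 0.29), and was chosen after its values were seen. In data simulated for the stimulation comparison on P(rGO), the same test recovered 54% of genes changed 2-fold and 12% of those changed 1.5-fold. Those data had 1 spread per gene for all groups, unlike the real libraries. With no low-count filter 168 genes were called on P(rGO), 3 on PEDOT:PSS, 18 on ITO and 137 for the mean effect. Every replicate 1 carries the prefix NB33 and every replicate 2 NB34 in the labels, which do not say what these stand for. In a fit of the 12 film libraries only, an alternative added after seeing the data, a replicate block gave 227 calls on P(rGO), 0 on PEDOT:PSS, 0 on ITO and 118 for the mean effect, against 2, 0, 0 and 2 without the block. Over all 16 libraries the block gave 0 calls for each. Without unstimulated ITO replicate 1, 3 genes were called on ITO, and without stimulated ITO replicate 2, 1 for the mean effect. The test for a difference in the effect of stimulation between films called 0 genes with edgeR (133 at an unadjusted p under 0.05) and 0 with DESeq2.

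Stimulated films were last set against differentiated plates. EPAS1 fell by 3.97 on the log2 scale on P(rGO) with ES (SE 0.63, adjusted p = 0.010) and by 3.78 on PEDOT:PSS with ES (SE 0.62, adjusted p = 0.0095). HSPA6, an inducible heat shock protein with a near-identical copy, had 2 counts on plates and 221, 253 and 615 on P(rGO), PEDOT:PSS and ITO with ES, ratios of 112 (counting interval 30.6 to 930), 132 (36.1 to 1094) and 278 (76.5 to 2297). Its levels there were 5.82 ± 0.032, 6.85 ± 2.4 and 14.4 ± 17 CPM (SD, n = 2), so the ITO replicates differed widely. On unstimulated P(rGO) HSPA6 was at 1.03 ± 0.56 CPM, against 0.0543 ± 0.077 on plates. The mean effect of stimulation on it was not called (log2 fold change 2.29, SE 0.49, edgeR adjusted p = 0.64). In the cell cycle list 10 of 31 genes fell on P(rGO) with ES (29 adjusted over the list alone; list adjusted p = 6.4e-30, 0.26 with an estimated correlation). EdgeR called 303 genes for P(rGO) with ES (151 higher), 226 for PEDOT:PSS with ES (143 higher) and 394 for ITO with ES (260 higher). Without plate replicate 1 the counts were 1, 16 and 46, and without plate replicate 2 they were 624, 349 and 359. Without stimulated replicate 1 they were 13, 18 and 117, and 215, 43 and 142 without stimulated replicate 2. HSPA6 lost its call for each film without either plate library, and on P(rGO) and PEDOT:PSS without either stimulated library too. EPAS1 lost its call on PEDOT:PSS without either stimulated library or plate replicate 1. On P(rGO) with ES, EPAS1 lost its call without plate replicate 1 and without stimulated replicate 1.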

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

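The tests of libraries shared by the effects, of the P(rGO) and ITO films alone, of 1 plate library, of plate replicate 1 alone, of the untreated libraries and of the splits with a replicate block were chosen only after the result was seen.

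The effect of stimulation on several gene lists differed between films in a test of the difference itself, and none of these differences held with an estimated correlation. Cell cycle genes had a median of -0.69 with stimulation on P(rGO), -0.49 on PEDOT:PSS and 0.06 on ITO, with adjusted p = 0.018 for P(rGO) against PEDOT:PSS (0.92 with an estimated correlation), 3.3e-17 for P(rGO) against ITO (0.52) and 8.4e-09 for PEDOT:PSS against ITO (0.94). Cholesterol biosynthesis genes had adjusted p = 0.047 for P(rGO) against PEDOT:PSS (0.92 with an estimated correlation) and 0.026 for PEDOT:PSS against ITO (0.94). Ribosomal protein genes had medians of 0.24, -0.06 and 0.18 on P(rGO), PEDOT:PSS and ITO, with adjusted p = 5.9e-12 for P(rGO) against PEDOT:PSS (0.72 with an estimated correlation) and 1.1e-08 for PEDOT:PSS against ITO (0.94). For P(rGO) against PEDOT:PSS the retinoic acid list had medians of -0.21 and 0.11 (adjusted p = 0.014, 0.72 with an estimated correlation) and the synapse list -0.11 and 0.01 (0.025, 0.72 with an estimated correlation). For P(rGO) against ITO the axon guidance list had medians of -0.08 and -0.01 (adjusted p = 0.022, 0.29 with an estimated correlation) and the extracellular matrix list -0.12 and 0.07 (0.0034, 0.52 with an estimated correlation). The share of uniquely placed reads assigned to no gene was 9.48% ± 0.75 (SD, n = 2) on P(rGO) with stimulation, 7.54% ± 0.37 without and 7.81% ± 0.09 on differentiated plates.

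Film libraries differed from plate libraries in 838, 267 and 764 genes (P(rGO), PEDOT:PSS and ITO). As given above, the counts fell furthest on each film without plate replicate 1, and also fell without either library of the film. Without plate replicate 2 they rose. The calls thus rested on plate replicate 1 more than on plate replicate 2, and on each film library as well. Each of these fits leaves 1 library in a group, so how much plate replicate 1 adds beyond the loss of a library cannot be told. Plate replicate 1 alone as the whole of the differences is argued against by a value: genes called without plate replicate 2 had a median difference from plate replicate 2 alone of 0.64 or more on each film, although those genes were selected with the same film libraries. Sharing plate libraries as the whole of the likeness between films is argued against by the correlation across genes, at least 0.46 with a different plate library for each film, where genes are not independent replicates. The coat or the vessel cannot be told apart from the film material, since no plate is stated to have the films' coat; the effects of the films, as differences of log2 CPM, correlated across genes at 0.83 or more. An effect of the film materials stays open.

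Across genes, stimulation effects and film effects had opposite signs, with correlations of -0.48, -0.32 and -0.44 on the same film, which share the unstimulated libraries. With the film effect from another film the highest of 6 correlations was -0.01, so shared libraries may account for the pattern over all films, and replicate differences correlated with film effects at sizes up to 0.15, as large as the smallest of the 6. For stimulation on P(rGO) and ITO alone the highest of 4 such correlations was -0.23, a value that sharing unstimulated libraries would not give; ordinary variation between replicates, at sizes up to 0.15, cannot be told apart there, because these films were picked after their values were seen. Genes are not independent replicates, and an effect of stimulation against that of the film stays open as a hypothesis.

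Over all 16 libraries no gene was called for the mean effect of stimulation by edgeR (1021 at an unadjusted p under 0.05, 7 genes by DESeq2). Among 100 of the 108 splits of the libraries within films, 7 had as many genes with an unadjusted p under 0.05 as the real 1021. The median of the others was 245, and the highest had 1908. That split follows the replicate numbers, labelled NB33 and NB34, a structure of the samples, and had 15 calls. With a replicate block, 32 splits exchange the labels of stimulation only within a film and a replicate number. Over the 16 libraries 2 of 32 had as many genes with an unadjusted p under 0.05 as the real 1139 (highest other 1410). Over the 12 film libraries only, 2 of 32 had as many as the real 2967 (highest other 3545), and 2 of 32 as many calls as the real 118 (highest other 596). Chance is therefore not excluded, without the block or with it. The highest other split with the block exchanged only the labels of ITO replicate 2 each time, and kept the real labels of all other pairs. The cause of its 596 calls was not tested. Counts of 0 calls decide nothing, since all 100 splits, and all 32 with the block over the 16 libraries, had to reach 0 (highest other 15 and 0).

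Without the untreated libraries the mean effect had 1 call and 1807 genes with an unadjusted p under 0.05, against 0 and 1021 with them. With a replicate block it had 1 call and 2308 such genes, against 0 and 1139. The spread of the untreated libraries as the cause of the 0 calls cannot be told apart from the low number of libraries or from small or absent effects. The calls stayed few while the genes with an unadjusted p under 0.05 rose.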

How the results depend on the processing

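The fits without the untreated libraries and with the 12 film libraries only were chosen only after the result was seen. Relative log expression scaling left all 15 counts of called genes within 1.5 times their values and 128 of 128 calls of named genes, as did DESeq2 for the named genes. Of 94 list calls for differentiation, the films and stimulation, 3 held with an estimated correlation and 45 with fry. For ITO with ES against plates 19 lists were called. Counted over all 35 lists, 1 passed with an estimated correlation, the mesenchymal list (adjusted p = 0.05), and 8 passed with fry. For P(rGO) with ES 12 lists were called, and counted over all 35 lists 0 and 1 passed. In the other comparisons none did. Named genes lost 168 of 512 calls with 1 replicate left out and 28 of 128 with only the groups compared. Depth limits little beside the 2 libraries per group.

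With no low-count filter 14 counts moved: the films against plates to 1625, 872 and 1430 (P(rGO), PEDOT:PSS and ITO), films with stimulation against plates to 1211, 896 and 1051, stimulation to 168, 3 and 18, its mean effect to 137, its difference between films to 13, PEDOT:PSS against P(rGO) to 16, ITO against P(rGO) to 48 and PEDOT:PSS against ITO to 48. Of the 168 calls, 167 were genes that the filter keeps; the cause was not tested. With DESeq2 the films against plates gave 1463, 664 and 1211, films with stimulation 830, 657 and 704, stimulation on P(rGO) 14, its mean effect 7 and PEDOT:PSS against ITO 2; the cause was not tested. With only the groups compared, differentiation gave 320, the mean effect of stimulation 2, films with stimulation 98 (P(rGO)) and 207 (ITO) and ITO against P(rGO) 1, from fits on fewer libraries. Over the 14 libraries without the untreated ones the films gave 2183, 954 and 1722, films with stimulation 1132, 879 and 991, stimulation on P(rGO) 1 and its mean effect 1, and 8 and 1 with a replicate block. With the 12 film libraries only, stimulation on P(rGO) gave 2 and the mean effect 2.

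With a replicate block over all 16 libraries the 15 counts stayed within 1.5 times, with differentiation at 5492, films at 938, 339 and 849, films with stimulation at 330, 311 and 502, and stimulation at 0. With the block over the 12 film libraries only, stimulation on P(rGO) gave 227 calls and the mean effect 118; the cause was not tested. Every replicate 1 is labelled NB33 and every replicate 2 NB34, with no meaning given, so a shared batch stays open. The numbers were not taken as pairs in the main model. Replicate differences of 28 pairs of groups correlated across genes at -0.19 to 0.29, 16 above 0.1 and 8 below 0, and 13 of 15 film pairs were above 0.1. Between a film with and without stimulation the correlation was 0.276 on P(rGO), 0.141 on PEDOT:PSS and 0.185 on ITO. Between different films it was 0.231 to 0.294 for the stimulated groups and 0.118 to 0.172 for the unstimulated groups. The values within a film were thus not particular to it, and a pairing by replicate number, within films or across them, stays open. Genes are not independent replicates.

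With 1 replicate left out, where the lone library is assumed to vary like the other groups, counts ranged over 1767 to 8050 for differentiation, 100 to 1023, 19 to 312 and 132 to 817 for P(rGO), PEDOT:PSS and ITO, 1 to 624, 16 to 349 and 46 to 359 for the same films with stimulation, 0 to 3 for stimulation on ITO, 0 to 1 for its mean effect, 0 to 9 for ITO against P(rGO) and 0 to 10 for PEDOT:PSS against ITO. The other 4 stayed at 0. Without plate replicate 1 the cell cycle list (adjusted p = 0.40, range down to 3.9e-09 without plate replicate 2) and the retinoic acid list (0.87, down to 8.6e-07 without plate replicate 2) changed direction for ITO against plates. Without stimulated ITO replicate 1 the heat shock list did so for stimulation on ITO (0.79, down to 2.4e-09 without stimulated replicate 2); the cause was not tested.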

Other observations

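Catecholamine identity genes, which make and store the transmitters of this cell lineage, fell in 3 of 18 cases on P(rGO) and 4 on ITO against plates (4 and 5 adjusted over the list alone; list adjusted p = 0.0013 and 0.00033, 0.20 and 0.13 with an estimated correlation), and in 0 on PEDOT:PSS, over all genes and adjusted over the list alone (list adjusted p = 0.0078, 0.20 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 4, 2 and 4 of 30 cases on P(rGO), PEDOT:PSS and ITO (4 on each film adjusted over the list alone; list adjusted p = 0.0060, 0.0038 and 0.0070, 0.29, 0.29 and 0.26 with an estimated correlation), COX6C on P(rGO) by 0.56 (SE 0.11), while the 13 mitochondrially encoded genes had medians of -0.44, -0.35 and -0.39 with none past the test, over all genes or adjusted over the list alone (list adjusted p = 0.0069, 0.0042 and 0.0041, 0.55, 0.49 and 0.51 with an estimated correlation). COX6C lost its call on P(rGO) without plate replicate 1 and without either P(rGO) replicate. The oxidative phosphorylation list lost its call without plate replicate 2 on P(rGO) and ITO, and the mitochondrially encoded list without plate replicate 1 on each film. The catecholamine and mitochondrially encoded lists lost their calls on PEDOT:PSS without PEDOT:PSS replicate 2.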
